A study of Mus musculus with 4 samples.

How the data were processed

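Intestinal epithelial cells from 2 mice were stained with CytoID, a dye that labels autophagic vesicles, and the brightest 15% (CytoID High) and dimmest 15% (CytoID Low) were sorted, per the labels. Cells of both mice carried hashtag antibodies, were pooled, and were run as 10x Genomics 3′ single-cell libraries, 1 per gate, so the gate and the library are confounded. Region of the intestine, sex, age, strain and genotype are not given in the sources used here.

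The count table deposited by the authors holds whole UMI counts for 31055 genes in 7403 cells. The deposited hashtag table holds antibody counts for 4 hashtags in the same cells, and the deposited matrices hold UMI counts for all 25516 barcodes. The authors' normalised table holds the natural log (ln) of 1 plus UMIs per 10000 of each cell's total, and it was not used for any comparison. The labels name Cell Ranger and Seurat without versions and list the genome build GRCh38, while the gene identifiers are mouse Ensembl identifiers, of which 30934 of 31055 were found in a mouse name table. The authors' cell filter is not stated. In the values, every kept cell had more than 500 genes and less than 20% mitochondrial UMIs. The authors kept 5112 of 11157 barcodes of the High library (45.8%) and 2291 of 14359 barcodes of the Low library (16.0%).

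A cell was given to a mouse when that mouse's pair of hashtags held at least 70% of its hashtag counts and at least 10 counts. This left out 708 High cells (13.8%) and 119 Low cells (5.19%). Scrublet (in scanpy 1.11.5) called 0 doublets among 5112 High cells and 17 among 2291 Low cells, 0.230% of all. At so low a rate doublets are not taken to be removed. Whether the authors removed any is not given in the sources used here, and doublets across types could remain. Of the cells, 6560 were used, 4404 High and 2156 Low.

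Cells were scaled to 10000 UMIs, log-transformed, reduced to 30 principal components of 2000 variable genes, joined to 15 neighbours and clustered with Leiden at resolution 1 (seed 1). Clusters were named from 15 fixed marker sets when at least 3 markers of a set were at least 2-fold above the other clusters and present in at least 10% of the cluster's cells, with the cluster's 10 leading genes as a check. The 20 clusters gave 8 classes, and 4 clusters stayed unnamed. Class names are rebuilt from these markers and are written with the ending "-like". A cluster drawn mostly from 1 library may mark that library and not a cell type. Markers that named a class are not independent evidence on that class.

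Raw counts were summed per mouse and gate, giving 4 sums, for all cells and within each class with at least 20 cells in every sum (5 classes). Genes were tested with edgeR 4.0.16 (quasi-likelihood, TMM, filterByExpr, limma 3.58.1, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment at 0.05 and no fold threshold. Log2 fold changes are High minus Low with a standard error (SE) from the fit, and CPM values are means ± SD of 2 mice. The p-values measure the spread between 2 mice per gate and not between sorts or libraries. The main model had no term for the mouse, and a model with mouse as a replicate block was the alternative. After removal of gate means, the values of the same mouse in both gates correlated across genes with r = 0.407 in all cells. Within enterocyte-like, stem-like, cycling progenitor-like, goblet-like and T or NK lymphocyte-like cells r was 0.174, 0.269, 0.235, 0.187 and 0.179. Genes are not independent replicates.

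The 25 gene lists were fixed in advance and cover autophagy machinery, autophagy receptors, lysosome, unfolded protein response, ATF4 stress targets, nuclear-encoded oxidative phosphorylation, the mitochondrial genome, glycolysis, fatty acid oxidation and ketogenesis, cholesterol synthesis, lipid absorption and lipoproteins, brush border and digestion, antimicrobial genes, mucus and goblet genes, crypt base stem cell genes, reserve, revival and fetal-like stem cell genes, secretory progenitor genes, G1/S and DNA replication, G2/M, DNA damage and p53 targets, NRF2 antioxidant genes, interferon response, MHC class II, dissociation and immediate early genes, and cytosolic ribosomal proteins. Each was tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 25 lists. Camera with an estimated correlation and fry were alternatives.

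Shares of cells and medians per cell were compared with two-sided exact permutation tests, for which 2 mice against 2 allow no p below 0.333. Shares per gate carry exact Clopper-Pearson 95% intervals, which cover counting error only. A ratio against a group at 0 counts is a lower limit set by 3 counts over the group, and a ratio against 1 to 3 counts is given with its 95% counting interval. Differences of the gate effect between enterocyte-like and stem-like cells were tested by an interaction term in edgeR. Other pairs of classes, and lists on the interaction, were added after the data were seen.

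Genes named in the text were chosen by a fixed rule. From the whole population come the 12 largest increases and the 12 largest decreases among called genes with a mean logCPM of at least 6 and the same direction in both mice. From each class come 4 in each direction. From each list come the 3 members with the smallest p, or, where none was called, the 2 with the highest mean. Members of both autophagy lists with a mean logCPM of at least 5 are given as a group, and Lgr5, Map1lc3b and Sqstm1 are always given. Not every gene that the rule gives is printed. Gene models without a symbol were counted and not named, except AY761184 and AY036118, which the rule did not list.

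Alternatives were the replicate block, DESeq2 1.42.0, RLE factors, no filter on low counts, doublets kept (with new clusters), each cell thinned to 5000 UMIs, all barcodes with at least 500 genes and at most 25% mitochondrial UMIs, epithelial cells only, an equal mix of the 5 tested classes (27 cells per class and sum), mitochondrial and ribosomal genes left out, resolutions 0.5 and 2, and each sum left out in turn. Alternatives chosen after seeing the data were removal of cells with high doublet scores, a hashtag share of 60%, Paneth-like clusters left out, the single shared cluster of a class, and the lists under the settings of the gene counts. The comparisons, lists, marker sets, rule for names and all other alternatives were chosen before the data were examined.

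The procedure was tested on simulated counts with the size and spread of 3 of the data sets. In the whole-population simulation 91% of genes raised or lowered 2-fold and 100% of those changed 4-fold were called, with 28 false calls among 245. For stem-like cells the 2 rates, false calls and all calls were 100%, 100%, 18 and 248, and for goblet-like cells 87%, 100%, 12 and 226. A raised list of 30 genes was found each time, and 0 of 20 random lists were called by camera at an unadjusted p of 0.05, with a preset or an estimated correlation. Random lists do not test the preset correlation on genes that vary together. Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used for the remaining steps.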

Results

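Messenger RNA was counted in single mouse intestinal epithelial cells sorted by CytoID, a dye for autophagic vesicles, into the brightest 15% (High) and the dimmest 15% (Low). The series title names the aim as comparing epithelial cells with high and low autophagy. Both gates hold cells of the same 2 mice, so that each comparison rests on 4 sums of cells, 2 High and 2 Low. In High, mouse 1 gave 2594 cells (78703663 UMIs) and mouse 2 gave 1810 (57174756). In Low they gave 1374 (33123416) and 782 (19230497). Each gate was a single droplet library, and no value can separate the gate from its library. The reporter genes tdTomato and YFP in the annotation had 0 counts in all 4 sums.

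The first question was which cell types each gate held. Paneth-like cells, the antimicrobial secretory cells of the crypt base, made up 16.4% ± 4.57 (SD, n = 2 mice) of High and 0.173% ± 0.0640 of Low, a ratio of 94.6 with 696 and 4 cells. Stem-like cells were 4.91% ± 1.33 of High and 39.2% ± 4.74 of Low, 7.98 times as many in Low. Absorptive enterocyte-like cells were 26.5% ± 9.47 of High and 7.59% ± 5.84 of Low. Cycling progenitor-like cells were 19.5% ± 3.75 and 7.55% ± 0.898. Mucus-making goblet-like cells were 13.8% ± 0.125 and 4.42% ± 0.645, a ratio of 3.12 that was 10.5 and 7.71 at clustering resolutions 0.5 and 2, 6.70 with doublets kept and 23.8 with all barcodes, where Low held 1.28%, 1.85%, 1.80% and 0.787%. Further classes were hormone-making enteroendocrine-like cells at 0.742% ± 0.123 and 2.74% ± 0.472 and T or NK lymphocyte-like cells at 2.80% ± 0.576 and 5.65% ± 2.13. With all barcodes the enterocyte-like ratio fell from 3.50 to 1.93, and the enteroendocrine-like ratio, Low over High, from 3.69 to 2.06. At resolution 0.5 no High cells were stem-like. In each of these classes both mice differed in the same direction (exact permutation p = 0.333, the smallest possible). Chemosensory tuft-like cells were 2.54% ± 0.708 and 1.76% ± 1.22 (exact permutation p = 0.667). Pooled over mice, the exact binomial 95% intervals for Paneth-like cells were 14.7% to 16.9% in High and 0.0506% to 0.474% in Low, and those for stem-like cells 4.14% to 5.42% and 36.3% to 40.4%. The intervals cover counting error only, and shares also depend on the gate, capture and the authors' filter.

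**Figure D1:**
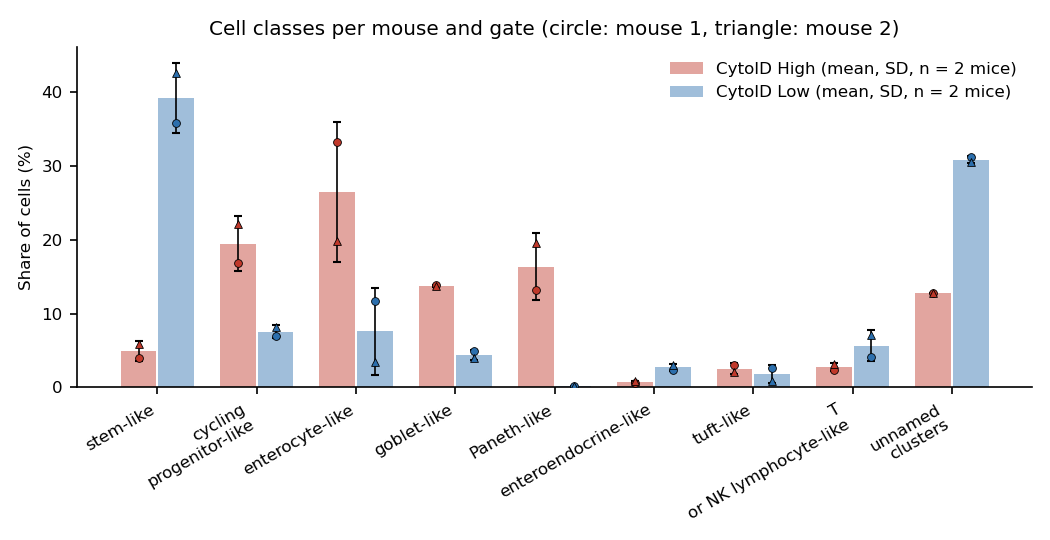
Share of cells in each class (percent of the cells of a mouse and gate) in CytoID High and Low, with a point per mouse and a bar at the mean. Paneth-like cells average 16.4% and 0.173%, and stem-like cells 4.91% and 39.2%.

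Unnamed clusters held 12.8% ± 0.0530 of High and 30.9% ± 0.467 of Low. Of the 4 unnamed clusters, cluster 2 had 3 High and 660 Low cells (30.5% of the cells of Low), cluster 7 had 391 and 7, cluster 16 had 124 and 1, and cluster 20 had 46 and 0. Within classes the gates also fell into different clusters. Clusters 3 and 4 held 577 and 549 enterocyte-like cells of High against 5 and 11 of Low, and cluster 12 held 91.5% of those of Low and 7.78% of those of High. Goblet-like cells were in cluster 6 (343 High and 86 Low) and cluster 11 (265 and 12), and cluster 13 held the lymphocyte-like cells of both gates.

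Median UMIs per cell were 26073 ± 1181 in High and 25668 ± 917 in Low (SD of 2 mice, exact permutation p = 0.667). Median genes per cell were 4387.5 ± 28.3 and 4775.5 ± 65.8, and the median mitochondrial share was 8.82% ± 0.135 and 7.95% ± 0.183 (exact permutation p = 0.333 for both). A few genes took different shares of the sums. Paneth marker genes held 13.4% and 20.9% of the UMIs of the High sums and 0.420% and 0.0625% of the Low sums, and the 10 most abundant genes held 20.7% and 28.3% against 10.6% and 10.8%. Cytosolic ribosomal protein genes held 14.4% and 13.6% in High and at least 20.4% in both sums of Low.

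The second question was which genes differ between all cells of the 2 gates. Genes of Paneth granules had the largest increases in High: Lyz1 (ENSMUSG00000069515), the Paneth lysozyme, was 158-fold higher (log2 7.31 ± 0.92 SE, n = 2 mice per gate, adjusted p = 0.0226). The goblet mucin Muc2 (ENSMUSG00000025515) was 13.6-fold higher (log2 3.77 ± 0.15, adjusted p = 0.00653). Genes of the crypt base were lower, with Olfm4 (ENSMUSG00000022026) 2.64-fold lower (log2 -1.40 ± 0.20, adjusted p = 0.0298) and the Wnt-responsive receptor Lgr5 (ENSMUSG00000020140) 2.53-fold lower (log2 -1.34 ± 0.21, adjusted p = 0.0328). The autophagy cargo receptor Sqstm1 (ENSMUSG00000015837) was 1.43-fold higher (log2 0.52 ± 0.07, adjusted p = 0.0249), and Map1lc3b (ENSMUSG00000031812), the LC3B that coats autophagosomes, was not called (log2 0.14 ± 0.07, adjusted p = 0.207, 126 ± 1.45 CPM in High and 114 ± 0.231 CPM in Low). Each value includes the change in the mix of classes.

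Of 13880 genes tested, 813 were higher and 533 lower in High at an adjusted p of 0.05. With mouse as a replicate block 3478 were higher and 2887 lower. Single sums moved these counts: 190 were higher and 22 lower without mouse 1 of High, 261 and 76 without mouse 2 of High, 477 and 230 without mouse 1 of Low, and 250 and 112 without mouse 2 of Low. Of the 72 named genes called in the whole population, 27, 40, 51 and 38 kept their call without these sums in turn. The genes Sqstm1, Map1lc3a, Atg13, Stx17, Tfe3, Hk2, Rpl35, mt-Nd3 and Ifitm3 lost it without every sum (adjusted p from 0.0525 to 0.237), Lgr5 without mouse 1 of High (0.0754) and mouse 1 of Low (0.0570), and Olfm4 without mouse 2 of Low (0.0563). With an equal mix of classes in both gates, with only the 5 tested classes and so no Paneth-like, enteroendocrine-like, tuft-like or unnamed cells, 67 genes were higher and 114 lower, and 20 of the 68 named genes with a value kept their call and direction. With that mix 10 of 20 list calls were lost, each given beside its list. With Paneth-like clusters left out, 421 were higher and 290 lower, 58 of 72 named genes kept their call, and 4 list calls were lost, both autophagy lists, ATF4 (adjusted p = 0.0717) and p53 (0.252).

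The other large increases were mostly alpha-defensins, antimicrobial peptides of Paneth granules. Defa22 (ENSMUSG00000074443) was 330-fold higher (log2 8.36 ± 0.80, adjusted p = 0.0141), Defa21 log2 8.27 ± 0.64 higher and Defa5 log2 7.82 ± 0.65 higher. Defa29, Defa36, Defa24, Defa26, Defa17 and Defa30 rose by log2 6.54 ± 1.20 to 7.32 ± 1.20. The defensin-like AY761184 rose by log2 7.35 ± 1.10, and the pentraxin Mptx2 by 7.46 ± 1.36 (adjusted p = 0.0418). Defensin genes are near-identical copies, and counts are uncertain between members. Lyz1, Mptx2 and 6 of these defensins are also among the markers that named the Paneth-like clusters.

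Among the decreases were the granins of hormone granules, Chga (log2 -3.94 ± 0.54, 15.3-fold lower) and Chgb (log2 -3.32 ± 0.32, 9.96-fold lower). With the equal mix, which holds no enteroendocrine-like cells, Chga and Chgb had log2 3.22 and 5.07, values from the other classes. The others of the 12, Cdca7, Slc12a2, Sox4, Nap1l1, Hmgn2, Erh, Ifitm3, Clca3b and AY036118, fell by log2 -0.75 ± 0.15 to -1.35 ± 0.10. Olfm4, Lgr5, Cdca7 and Slc12a2 are among the stem cell markers, and Chga and Chgb among the enteroendocrine markers, that named clusters.

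**Figure D2:**
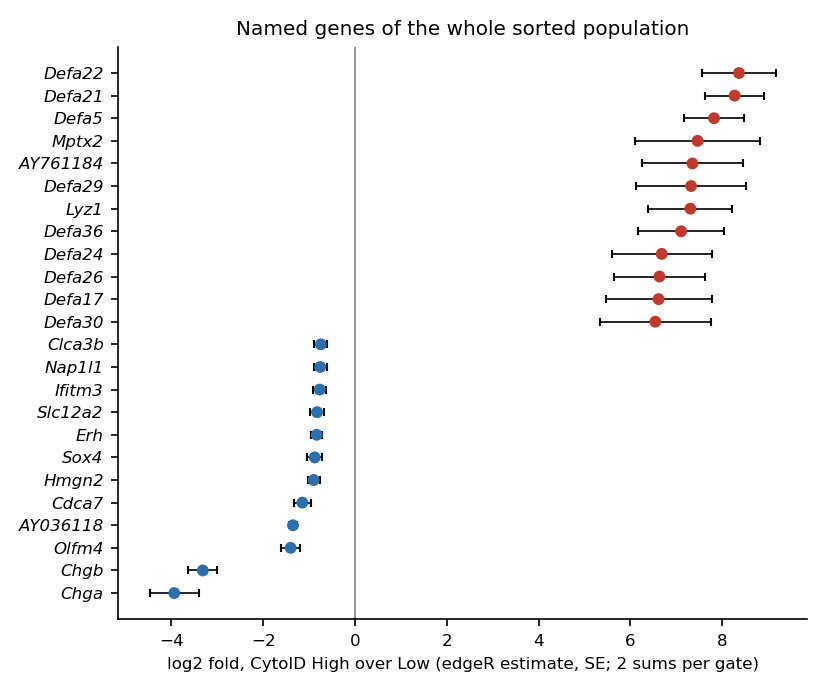
Log2 fold change, High minus Low, of the genes with the largest increases and decreases in the whole population, with bars for the standard error of the edgeR fit (2 mice per gate). Defa22 stands highest at 8.36 and Chga lowest at -3.94.

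The genes of autophagy itself were examined as 2 lists. Of 40 autophagy machinery genes tested, 5 were higher, 0 lower and 35 not called (6 higher adjusted over the list alone), with a median log2 of 0.13 (adjusted p = 0.00923 and adjusted p = 0.603 with an estimated correlation). With an equal mix of classes the list pointed down without a call (median -0.0381, adjusted p = 0.965). Its call was also lost with the replicate block (0.0546), without mouse 1 of Low (0.0624) and mouse 2 of Low (0.0776), after thinning to 5000 UMIs per cell (0.140) and with Paneth-like clusters left out (0.0881). Of 20 autophagy receptors 1 was higher, 0 lower and 19 not called (1 adjusted over the list alone), with a median of 0.24 (adjusted p = 0.0250 and adjusted p = 0.603 with an estimated correlation). This call was lost with the equal mix (median 0.0571, 0.586), the block (0.0546), without mouse 1 of High (0.0784) and mouse 2 of Low (0.224), after thinning (0.140) and with Paneth-like clusters left out (0.186). The block gave more single genes: 12 machinery genes and 12 receptors were higher and 0 lower, among them Nbr1 (log2 0.30, adjusted p = 0.00453) and Rtn3 (log2 0.24, adjusted p = 0.0103). The LC3 family member Map1lc3a rose by log2 0.55 ± 0.08 (adjusted p = 0.0313), the initiation factor Atg13 by 0.58 ± 0.09 (adjusted p = 0.0350) and the fusion protein Stx17 by 0.35 ± 0.07 (adjusted p = 0.0439). Among the 23 members of both lists with a mean logCPM of at least 5, 4 were higher and 19 not called, with log2 values from -0.02 to 0.52 (15 higher with the replicate block). The 4 were Sqstm1, Stx17, Gabarap (log2 0.49 ± 0.10, adjusted p = 0.0472) and Tmem41b (log2 0.46 ± 0.09, adjusted p = 0.0441). With the equal mix Sqstm1, Map1lc3a and Atg13 were not called (log2 0.20, 0.33 and 0.20), and Stx17 had log2 -0.10.

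Of 42 lysosome genes 5 were higher and 37 not called (5 adjusted over the list alone, 24 with the block, median log2 0.23, adjusted p = 0.000291, adjusted p = 0.603 with an estimated correlation). The proton pump subunit Atp6v0d1 (log2 0.67 ± 0.09, adjusted p = 0.0280) and the lysosome regulator Tfe3 (log2 0.67 ± 0.10) had the smallest p-values. Of 23 unfolded protein response genes 8 were higher and 15 not called (14 adjusted over the list alone, 18 with the block, median 0.46, adjusted p = 4.76e-07, adjusted p = 0.447 with an estimated correlation). They included Ern2, the goblet cell stress sensor (log2 2.69 ± 0.21, adjusted p = 0.0109) and Edem1 (log2 1.12 ± 0.07, adjusted p = 0.00798). With the equal mix the median was 0.0308 (adjusted p = 0.584), and Edem1 had log2 -0.23. Of 20 ATF4 stress targets 6 were higher, 1 lower and 13 not called (11 and 1 adjusted over the list alone, 12 and 2 with the block, median 0.46, adjusted p = 0.00014, adjusted p = 0.445 with an estimated correlation and 0.260 with the equal mix). Nupr1, a stress-induced chromatin protein, was 42.8-fold higher (log2 5.42 ± 0.26, adjusted p = 0.00653) and the glutathione-cleaving Chac1 log2 4.14 ± 0.30 higher.

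Secretory genes moved most. Of 19 antimicrobial genes 12 were higher and 7 not called (14 adjusted over the list alone, median log2 1.36, adjusted p = 6.18e-09, adjusted p = 0.445 with an estimated correlation), including Zg16 (log2 2.83 ± 0.29, adjusted p = 0.0162). Of 17 mucus and goblet genes 15 were higher and 2 not called (15 adjusted over the list alone, median 2.22, adjusted p = 2.79e-20, adjusted p = 0.445 with an estimated correlation). Their median was 0.0648 (adjusted p = 0.283) with the equal mix. Spink4, a goblet cell peptide, was 21.6-fold higher (log2 4.43 ± 0.15, adjusted p = 0.00653). Of 12 secretory progenitor genes 2 were higher, 2 lower and 8 not called (5 and 4 adjusted over the list alone and with the block). The median of that list was -0.07 while its mean was 0.21 and its test pointed up (adjusted p = 0.611), so that the signs differed. The goblet regulators Spdef (log2 2.40 ± 0.14, adjusted p = 0.00798) and Atoh1 (log2 2.47 ± 0.18, adjusted p = 0.0104) were higher, and the endocrine Insm1 (log2 -1.59 ± 0.14, adjusted p = 0.0125) was lower. Their log2 values were -0.95, -0.23 and 0.90 with the equal mix, where the list was called lower (median -0.71, adjusted p = 6.16e-06).

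Of 21 crypt base stem cell genes 11 were lower and 10 not called (16 lower adjusted over the list alone, 18 with the block, median log2 -0.83, adjusted p = 2.96e-09, adjusted p = 0.603 with an estimated correlation). Of 14 reserve, revival and fetal-like stem cell genes 6 were higher, 1 lower and 7 not called (6 and 3 adjusted over the list alone, median 0.75, adjusted p = 0.00923, adjusted p = 0.447 with an estimated correlation). Of 23 G1/S and DNA replication genes 6 were lower and 17 not called (1 higher and 10 lower adjusted over the list alone, 1 and 18 with the block, median -0.50, adjusted p = 3.04e-06, adjusted p = 0.603 with an estimated correlation). Of 22 G2/M genes 8 were higher and 14 not called (17 and 1 adjusted over the list alone and with the block, median 0.52, adjusted p = 2.49e-07, adjusted p = 0.603 with an estimated correlation). Ube2c (log2 1.16 ± 0.13, adjusted p = 0.0194) and Aurkb (log2 1.32 ± 0.16) led that list. The list pointed down without a call (median -0.0210, adjusted p = 0.586) with the equal mix, and Aurkb had log2 -0.17.

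Of 23 dissociation and immediate early genes 12 were higher and 11 not called (16 and 1 adjusted over the list alone, median log2 0.73, adjusted p = 1.32e-07, adjusted p = 0.447 with an estimated correlation). The stress factor Atf3 (log2 1.97 ± 0.08, adjusted p = 0.00653) was among them. Of 21 p53 targets and DNA damage genes 7 were higher and 14 not called (10 and 1 adjusted over the list alone, 11 and 3 with the block, median 0.31, adjusted p = 0.00178, adjusted p = 0.445 with an estimated correlation and 0.506 with the equal mix). Of 23 NRF2 antioxidant genes 5 were higher and 18 not called (9 adjusted over the list alone, 14 with the block, median 0.36, adjusted p = 0.000291, adjusted p = 0.603 with an estimated correlation and 0.0600 with the equal mix). Of 21 cholesterol synthesis genes 10 were higher and 11 not called (13 adjusted over the list alone, 16 with the block, median 0.38, adjusted p = 1.38e-06, adjusted p = 0.447 with an estimated correlation).

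Several metabolic lists were called with few or no single genes called by edgeR. Of 20 lipid absorption genes 0 were called (9 higher adjusted over the list alone, 15 higher with the replicate block, median log2 0.78, adjusted p = 0.000251, adjusted p = 0.603 with an estimated correlation). The fatty acid binding protein Fabp1 had log2 1.34 ± 0.41 (adjusted p = 0.0886, 9.45e-05 with the block). Of 23 brush border genes 0 were called (0 adjusted over the list alone, 19 higher with the block, median 0.80, adjusted p = 0.000202, adjusted p = 0.630 with an estimated correlation), with the sucrase Sis at log2 1.27 ± 0.40 (adjusted p = 0.0932, 8.75e-05 with the block). Both lists were called in the opposite direction with the equal mix, lipid absorption with a median of -0.18 (adjusted p = 0.00114) and brush border with -0.52 (adjusted p = 1.53e-07), and Fabp1 and Sis had log2 -0.34 and -0.30. Of 24 fatty acid oxidation genes 0 were called (0 adjusted over the list alone, 17 higher and 1 lower with the block, median 0.33, adjusted p = 0.00398, adjusted p = 0.661 with an estimated correlation). The list's call was lost without mouse 1 of High (0.0737) and without mouse 2 of Low (0.103). At an unadjusted p under 0.05, and by DESeq2 after adjustment, 13 and 9 lipid absorption genes, 8 and 5 brush border genes and 10 and 5 fatty acid oxidation genes passed.

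Of 43 nuclear oxidative phosphorylation genes 0 were called (0 adjusted over the list alone, 15 higher with the block, median log2 0.21, adjusted p = 0.00969, adjusted p = 0.827 with an estimated correlation and 0.350 with the block). The list's call was lost without mouse 1 of High (0.270), mouse 1 of Low (0.0790) and mouse 2 of Low (0.0864). Of 16 glycolysis genes 1 was higher, 1 lower and 14 not called (8 and 1 adjusted over the list alone, 10 and 1 with the block, median 0.43, adjusted p = 0.0158, adjusted p = 0.603 with an estimated correlation and 0.134 with the block). Its call was lost without mouse 1 of High (0.0784) and mouse 1 of Low (0.0844), and the phosphofructokinase Pfkp rose by log2 0.96 ± 0.17 while the hexokinase Hk2 fell by log2 -0.38 ± 0.07. Of 13 mitochondrial genome genes 1 was higher and 12 not called (6 and 2 adjusted over the list alone, 7 and 3 with the block, median 0.17, adjusted p = 0.413, and 0.934 in the opposite direction with the block), the one being mt-Nd3 (log2 0.45 ± 0.08). Of 42 ribosomal protein genes 1 was lower and 41 not called (0 adjusted over the list alone, 6 lower with the block, median -0.10, adjusted p = 0.0633). Rpl35 was the one at log2 -0.51 ± 0.09 (adjusted p = 0.0409), and the list's adjusted p was 0.0403 without mouse 1 of Low. Of 20 interferon response genes 0 were called (0 adjusted over the list alone, 9 higher with the block, median 0.41, adjusted p = 0.214). The interferon list passed without mouse 2 of High (0.00657) and without mouse 1 of Low (0.0118). Of 7 MHC class II genes 0 were called (0 adjusted over the list alone, 2 lower with the block, median -0.07, adjusted p = 0.728). The MHC class II list was called lower with the equal mix (median -0.35, adjusted p = 0.00240), where the interferon (0.176), ribosomal (0.176) and mitochondrial genome (0.702) lists changed direction without a call. At an unadjusted p under 0.05, and by DESeq2, 7 and 2 oxidative phosphorylation genes, 1 and 1 interferon genes and 0 and 0 MHC class II genes passed.

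**Figure D3:**
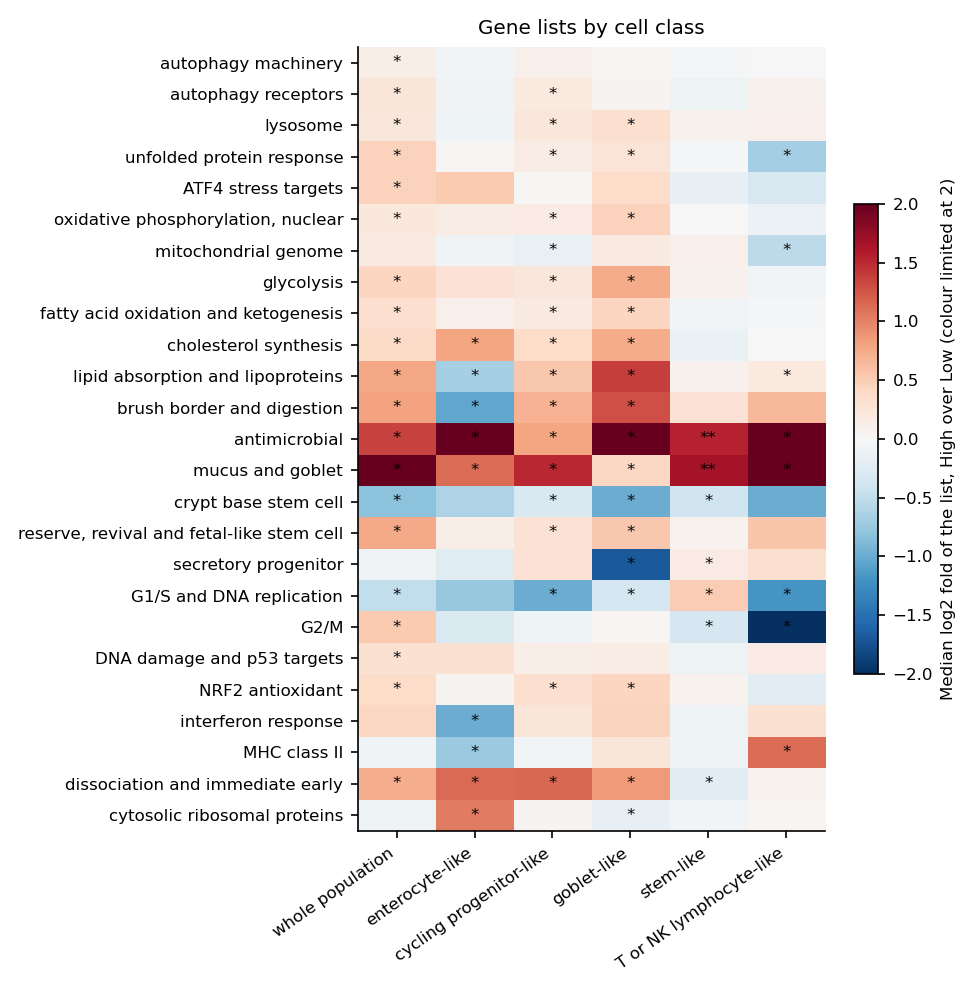
Median log2 fold change, High minus Low, of each gene list in the whole population and in the 5 tested classes, with marked values for lists past an adjusted p of 0.05 by camera with a preset correlation. In the whole population the mucus list is highest at 2.22 and the crypt base list lowest at -0.83.

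RNA of Paneth and goblet genes in cells of other classes, called free RNA here, differed between the gates in each class. T or NK lymphocyte-like cells, which should lack Paneth genes, carried 51.0 Paneth marker UMIs per cell in High and 0.850 in Low, and 100% and 35.4% of them held at least 1 such UMI at median depths of 2609.5 and 4399 UMIs. Their goblet marker UMIs were 19.2 and 0.823 per cell. Enterocyte-like cells carried 101 and 1.40 (100% and 46.3% of cells, median depths 23982 and 14840.5), cycling progenitor-like cells 153 and 4.44, and stem-like cells 129 and 14.9. Goblet-like cells carried 559 and 66.3, set apart from free RNA here. Paneth-like cells themselves carried 29898 in High and 31326 in Low, the latter from 4 cells. Counts of Paneth genes in another class need not be its own expression.

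**Figure D4:**
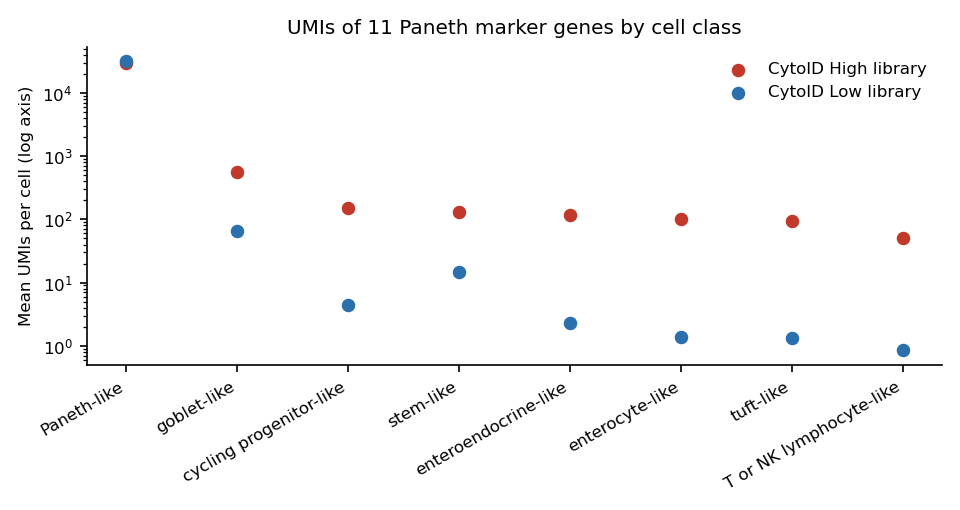
Paneth marker UMIs per cell (log axis) in each class of CytoID High and Low. Values in High run from 51.0 in T or NK lymphocyte-like cells to 559 in goblet-like cells outside the Paneth-like class, and each is above the value of the same class in Low.

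Within enterocyte-like cells, the question was whether absorptive cells differ between the gates. Ada, an enzyme of the villus tip, was 107-fold lower in High (log2 -6.74 ± 0.38, adjusted p = 0.000246), and the apolipoprotein Apoa4 5.72-fold lower (log2 -2.52 ± 0.23, adjusted p = 0.00164). The immediate early gene Atf3 was 3.14-fold higher (log2 1.65 ± 0.14, adjusted p = 0.00117), and all 42 ribosomal protein genes were higher (median log2 1.05). The sums hold 862 and 359 cells of High, mostly of clusters 3 and 4, and 161 and 27 of Low, mostly of cluster 12, so that different clusters are compared. In cluster 12 alone Ada was still called (log2 -4.90), and Apoa4 (log2 -0.73, adjusted p = 0.331) and Atf3 (log2 1.48, adjusted p = 0.102) were not.

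Of 9896 genes 650 were higher and 816 lower. Single sums left out gave from 200 and 288 (mouse 2 of High) to 1615 and 1514 (mouse 2 of Low). In cluster 12 alone 21 were higher and 8 lower of 6350, and 10 of 57 named genes kept their call. Further decreases, also leading genes of cluster 12, were Cyp3a11 (log2 -3.67 ± 0.24, 12.7-fold), Dnase1 (log2 -2.91 ± 0.26) and Selenop (log2 -2.80 ± 0.38). The largest increases were Paneth genes: Defa17, AY761184 (log2 7.40 ± 0.31), Defa29 (log2 6.66 ± 0.31) and Defa24 (log2 6.41 ± 0.48), which moved with the free RNA. Defa17 had 1 count in Low, a ratio of 374 with a counting interval from 67.1 to 14780.

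Of 23 brush border genes 16 were lower (20 adjusted over the list alone, median log2 -1.05, adjusted p = 4.47e-14, adjusted p = 0.502 with an estimated correlation), such as the trehalase Treh (log2 -1.94 ± 0.18). Of 19 lipid absorption genes 8 were lower and 1 higher (13 and 1 adjusted over the list alone, median -0.66, adjusted p = 4.82e-09, adjusted p = 0.383 with an estimated correlation). Of 21 cholesterol synthesis genes 11 were higher (16 adjusted over the list alone, median 0.79, adjusted p = 1.45e-08, adjusted p = 0.502 with an estimated correlation). Of 22 immediate early genes 16 were higher (16 adjusted over the list alone, median 1.14, adjusted p = 4.43e-16, adjusted p = 0.383 with an estimated correlation). In cluster 12 alone 4 of 9 list calls stayed, ribosomal (median 0.45, adjusted p = 2.26e-13), immediate early (0.15, 0.0191), antimicrobial and mucus genes. The lipid absorption list pointed up (median 0.04, adjusted p = 0.767), and the calls of brush border (median -0.15, 0.0725), cholesterol synthesis (0.29, 0.357), MHC class II (-0.07, 0.767) and interferon genes (-0.28, 0.767) were lost. There 0 of 17 immediate early genes were called by edgeR, where the cluster had 694 genes at an unadjusted p under 0.05. In the whole class the ribosomal list had an adjusted p of 1.45e-37 (0.502 with an estimated correlation).

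MHC class II genes were lower in 5 of 7 (6 adjusted over the list alone, median log2 -0.74, adjusted p = 3.03e-05, adjusted p = 0.502 with an estimated correlation). Interferon genes were lower in 6 of 15 (7 adjusted over the list alone, median -0.99, adjusted p = 0.00073, adjusted p = 0.635 with an estimated correlation), and this list call was lost without mouse 1 of Low (0.116). Antimicrobial genes (8 higher and 2 lower of 17, adjusted p = 3.82e-14, adjusted p = 0.383 with an estimated correlation) and mucus genes (5 and 2 of 14, adjusted p = 7.85e-06, adjusted p = 0.383 with an estimated correlation) moved with the free RNA. The autophagy lists were not called as lists. The receptors Optn (log2 -0.96 ± 0.14, adjusted p = 0.00671) and Nbr1 (log2 -0.56 ± 0.12, adjusted p = 0.0205) were lower. In cluster 12 alone neither was called (Optn log2 -0.84, adjusted p = 0.273, Nbr1 -0.23, 0.705), and Nbr1 lost its call with DESeq2 (0.138) and without 3 of the 4 sums (0.222 to 0.276), while Map1lc3b (log2 0.16 ± 0.12, adjusted p = 0.409) and Sqstm1 (log2 0.28 ± 0.13, adjusted p = 0.179) were not called. Of the 68 named genes called in this class, 43, 44, 46 (of 67) and 68 kept their call without mice 1 and 2 of High and mice 1 and 2 of Low in turn.

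Within stem-like cells, the comparison asked whether stem cells with bright and dim staining differ. Counts of secretory genes were higher in High: Chgb, a granin of endocrine granules, was 57.5-fold higher (log2 5.85 ± 0.14, adjusted p = 5.83e-12), Zg16, a goblet and Paneth lectin, 31.3-fold higher (log2 4.97 ± 0.10, adjusted p = 1.57e-12) and Muc2 27.0-fold higher (log2 4.76 ± 0.14). Free RNA limits this: Zg16 and Muc2 had log2 7.02 and 6.06 in lymphocyte-like cells. Chgb had log2 0.96 (adjusted p = 0.148) with doublets kept, and enteroendocrine marker UMIs per stem-like cell averaged 37.6 and 0.685 with medians of 1 and 0. The stem cell gene Olfm4 was 1.51-fold lower (log2 -0.60 ± 0.07, adjusted p = 0.000257), and Lgr5 1.72-fold lower (log2 -0.79 ± 0.18, adjusted p = 0.0299). The call of Lgr5 was lost without mouse 2 of High (log2 -0.55, adjusted p = 0.199), without mouse 1 of Low (log2 -0.52, adjusted p = 0.120), with DESeq2 (0.0766) and after thinning (0.504). All 209 High cells came from cluster 14, and 97.1% of Low cells from cluster 1, which had 0 High cells.

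Of 10925 genes 197 were higher and 80 lower, and 492 and 370 with the replicate block. Single sums left out gave from 123 and 50 (mouse 1 of High) to 228 and 130 (mouse 2 of Low). The endocrine progenitor factor Neurog3 had 1 count in Low and 88 in High, a ratio of 279 with a counting interval from 48.7 to 11130. Insm1 had 2 and 70 counts, a ratio of 111 with an interval from 29.6 to 933. Decreases included Ccnb2, a mitotic cyclin (log2 -0.92 ± 0.10, adjusted p = 0.000128) and AY036118 (log2 -1.26 ± 0.12).

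The antimicrobial list (12 of 19 higher, 15 adjusted over the list alone, median log2 1.54, adjusted p = 1.04e-86) and the mucus list (8 of 15 higher, 9 adjusted over the list alone, median 1.66, adjusted p = 4.35e-138) were the only list calls to hold with an estimated correlation (adjusted p = 0.0313 for each). Both moved with the free RNA. Of 23 G1/S genes 14 were higher (23 adjusted over the list alone, median 0.51, adjusted p = 2.18e-20, adjusted p = 0.414 with an estimated correlation). Of 22 G2/M genes 4 were lower and 1, Top2a (log2 0.81 ± 0.13), was higher (9 and 3 adjusted over the list alone, median -0.33, adjusted p = 0.000673, adjusted p = 0.826 with an estimated correlation), a call lost without mouse 1 of High (0.406). Of 21 crypt base genes 8 were lower (14 adjusted over the list alone, median -0.40, adjusted p = 1.08e-08, adjusted p = 0.666 with an estimated correlation). Secretory progenitor genes were higher in 2 of 9 (2 adjusted over the list alone, median 0.16, adjusted p = 4.57e-05, adjusted p = 0.414 with an estimated correlation), and after thinning the list pointed down without a call (median -0.00119, adjusted p = 0.493). Immediate early genes were lower in 2 of 22 (6 adjusted over the list alone, median -0.23, adjusted p = 0.000739, adjusted p = 0.632 with an estimated correlation). That list call was lost without mouse 2 of Low (0.128), and 12 of its genes were lower with the block. The block added list calls for lipid absorption (higher, adjusted p = 0.0240 against 0.218), brush border (higher, 0.0240 against 0.0696) and ribosomal proteins (lower, 0.000138 against 0.0696). The autophagy lists were not called, and neither were Map1lc3b (log2 -0.20 ± 0.08, adjusted p = 0.315) and Sqstm1 (log2 -0.26 ± 0.12, adjusted p = 0.359). Of 37 named genes called, 28, 30, 30 and 32 kept their call without mice 1 and 2 of High and mice 1 and 2 of Low in turn.

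Within cycling progenitor-like cells, replication genes were lower and immediate early genes higher in High. All 23 G1/S genes were lower (23 adjusted over the list alone, median log2 -0.99, adjusted p = 6.21e-25, adjusted p = 0.484 with an estimated correlation), with the chromatin remodeller Hells 2.59-fold lower (log2 -1.37 ± 0.17, adjusted p = 0.00137). Atf3 was 4.17-fold higher (log2 2.06 ± 0.16, adjusted p = 7.73e-05). Sqstm1 was 1.77-fold higher (log2 0.82 ± 0.17, adjusted p = 0.0158) and Map1lc3b 1.26-fold higher (log2 0.33 ± 0.09, adjusted p = 0.0371). High cells came mostly from clusters 5 and 9 and 85.5% of Low cells from cluster 15, which had 1 High cell.

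Of 11123 genes 573 were higher and 803 lower, and 1417 and 1478 with the replicate block. Single sums left out gave 166 to 576 and 328 to 692. The call of Map1lc3b was lost without each of the 4 sums (adjusted p from 0.0915 to 0.225), with DESeq2 (0.174) and after thinning (0.154), and that of Sqstm1 without mouse 2 of Low (0.0750) and after thinning (0.179). Replication histones, near-identical copies with uncertain single values, fell (Hist1h2ae log2 -2.13 ± 0.14). The proliferation gene Top2a (log2 -1.06 ± 0.08, adjusted p = 6.21e-05) and AY036118 (log2 -2.34 ± 0.17) were lower. The largest increases were Defa17 (log2 6.07 ± 0.21), AY761184 (log2 5.28 ± 0.16), Defa29 (log2 5.12 ± 0.17) and Defa24 (log2 5.09 ± 0.11), which moved with the free RNA.

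Of 22 immediate early genes 14 were higher (17 adjusted over the list alone, median log2 1.15, adjusted p = 4.72e-22, adjusted p = 0.0699 with an estimated correlation). NRF2 genes were higher in 9 of 22 (10 adjusted over the list alone, median 0.33, adjusted p = 1.9e-05, adjusted p = 0.484 with an estimated correlation). Lipid absorption genes were higher in 9 of 19 (11 adjusted over the list alone, median 0.53, adjusted p = 3.41e-06, adjusted p = 0.505 with an estimated correlation), and cholesterol synthesis genes in 4 of 21 (4 adjusted over the list alone, median 0.37, adjusted p = 0.000343, adjusted p = 0.321 with an estimated correlation). Of 18 autophagy receptors 1, Sqstm1, was higher (1 adjusted over the list alone, median 0.19, adjusted p = 0.0275, adjusted p = 0.505 with an estimated correlation), a list call lost without mouse 1 of High (0.0835), without mouse 2 of Low (0.0805) and after thinning (0.0762). The machinery list was not called, with the autophagosome proteins Vmp1 (log2 0.52 ± 0.10, adjusted p = 0.00994) and Gabarap (log2 0.35 ± 0.08, adjusted p = 0.0232) higher and Uvrag (log2 -0.88 ± 0.17, adjusted p = 0.0112) lower. Gabarap lost its call without each of the 4 sums (0.0596 to 0.240), Vmp1 (0.0644 and 0.0686) and Uvrag (0.0506 and 0.0645) without 2, and Uvrag with DESeq2 (0.0776). Of 73 named genes called, 49, 62, 46 and 44 kept their call without mice 1 and 2 of High and mice 1 and 2 of Low in turn.

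Also higher were lysosome (median log2 0.23, adjusted p = 0.0107), oxidative phosphorylation (0.16, 0.00295), reserve stem cell (0.28, 0.0124) and brush border genes (0.70, 7.88e-05). With an estimated correlation their adjusted p-values were 0.505, 0.596, 0.484 and 0.505, and with the block 12, 20, 4 and 13 of their genes were higher, against 3, 7, 3 and 3. Unfolded protein response genes (median 0.15, adjusted p = 0.00715, adjusted p = 0.505 with an estimated correlation) lost the call without mouse 2 of High (0.0755) and mouse 1 of Low (0.0965). Glycolysis (median 0.22, adjusted p = 0.0128, adjusted p = 0.505 with an estimated correlation) lost it without mouse 1 of Low (0.275). Fatty acid oxidation (median 0.17, adjusted p = 0.00715, adjusted p = 0.586 with an estimated correlation) lost it without mouse 1 of High (0.172) and mouse 2 of Low (0.0984). The mitochondrial genome was lower (median -0.15, 5 of 13 genes, adjusted p = 0.00589, adjusted p = 0.505 with an estimated correlation) and lost the call without mouse 2 of High (0.0532). Crypt base genes were lower (median -0.31, 5 of 21 genes, adjusted p = 0.00153, adjusted p = 0.506 with an estimated correlation). Antimicrobial (median 0.80, 11 of 19 genes, adjusted p = 6.48e-70) and mucus genes (median 1.51, 8 of 16 genes, adjusted p = 4.4e-42) were higher with the free RNA (adjusted p = 0.0699 for each with an estimated correlation). Thinning also ended the calls of cholesterol synthesis (0.0735), crypt base (0.105) and reserve stem cell genes (0.136).

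Within goblet-like cells, RNA of absorptive genes was higher in High and progenitor genes were lower. Enterocyte marker UMIs per cell were 172 in High and 47.3 in Low at median depths of 21226 and 11679.5, against 3.65 and 4.30 in lymphocyte-like cells of the same libraries, and enterocyte-like cells were 26.5% of High and 7.59% of Low. Muc2 was 2.26-fold higher (log2 1.17 ± 0.15, adjusted p = 0.00644) and Sox4, a factor of early secretory progenitors, 8.57-fold lower (log2 -3.10 ± 0.17, adjusted p = 0.000165). The Notch ligand Dll1, which marks secretory progenitors, was 3.53-fold lower (log2 -1.82 ± 0.14, adjusted p = 0.00104). These values depend on which Low cells count as goblet-like. With doublets kept and new clusters, 40 did in place of 98, and Muc2 had log2 0.36 (adjusted p = 0.361), Sox4 -1.15 and Dll1 -1.44 (0.0339 and 0.00435). At resolution 2, 41 did, and a cluster named tuft-like (7 High and 95 Low) had Neurog3, Sox4 and Kit among its 10 leading genes. High cells came from clusters 6 and 11 and most Low cells from cluster 6, where the same comparison alone gave 918 genes higher and 617 lower of 10158 and 58 of 64 named genes kept their call.

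Of 10428 genes 707 were higher and 555 lower, and 1387 and 1011 with the replicate block. Single sums left out gave 274 to 562 lower. With doublets kept (16 more cells, all Low) and new clusters, 49 were higher and 18 lower, and 13 of 64 named genes kept their call. Class membership may weigh more here than doublets. The largest increases were Mptx2, with 1 count in Low (ratio 181, counting interval 32.4 to 7150), Defa30 (log2 7.47 ± 0.21), AY761184 (log2 7.46 ± 0.29) and Defa29 (log2 6.63 ± 0.41), which moved with the Paneth RNA in these cells.

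Of 12 secretory progenitor genes 9 were lower (11 adjusted over the list alone, median log2 -1.68, adjusted p = 3.61e-24, adjusted p = 0.184 with an estimated correlation). Crypt base genes were lower in 9 of 20 (10 adjusted over the list alone, median -0.996, adjusted p = 4.13e-11, adjusted p = 0.312 with an estimated correlation). Oxidative phosphorylation genes were higher in 21 of 43 (33 adjusted over the list alone, median 0.47, adjusted p = 2.2e-12, adjusted p = 0.406 with an estimated correlation). Glycolysis genes were higher in 6 of 14 (10 adjusted over the list alone, median 0.75, adjusted p = 1.1e-06, adjusted p = 0.312 with an estimated correlation). Lipid absorption genes were higher in 11 of 19 (14 adjusted over the list alone, 18 with the block, median 1.38, adjusted p = 1.41e-13, adjusted p = 0.312 with an estimated correlation). Brush border genes were higher in 10 of 23 (16 adjusted over the list alone, 21 with the block, median 1.29, adjusted p = 9.59e-12, adjusted p = 0.406 with an estimated correlation), and cholesterol synthesis genes in 10 of 21 (15 adjusted over the list alone, median 0.74, adjusted p = 4.59e-09, adjusted p = 0.312 with an estimated correlation). Immediate early genes were higher in 12 of 22 (14 adjusted over the list alone, median 0.85, adjusted p = 9.59e-12, adjusted p = 0.406 with an estimated correlation). The revival list was higher (median 0.55, adjusted p = 0.00179, adjusted p = 0.312 with an estimated correlation).

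NRF2 genes were higher in 9 of 22 (median log2 0.42, adjusted p = 3.03e-05, adjusted p = 0.312 with an estimated correlation), and antimicrobial genes in 12 of 17 (median 2.33, adjusted p = 1.14e-38, adjusted p = 0.121 with an estimated correlation). Mucus genes (4 of 16 higher, median 0.41, adjusted p = 0.0237, adjusted p = 0.610 with an estimated correlation) lost the call without mouse 2 of High (0.270) and were called in the opposite direction with doublets kept (median -0.24, adjusted p = 0.00178). Lysosome genes (5 of 42, median 0.31, adjusted p = 0.0168, adjusted p = 0.312 with an estimated correlation) lost it without mouse 1 of Low (0.0521). Unfolded protein response genes (2 of 23, median 0.28, adjusted p = 0.0276, adjusted p = 0.690 with an estimated correlation) lost it without mouse 2 of High (0.288) and mouse 1 of Low (0.109), in cluster 6 alone (0.864) and after thinning (0.0603), and with doublets kept they pointed down without a call (median -0.0709, 0.324). Fatty acid oxidation genes (3 higher and 1 lower of 24, 11 and 1 with the block, median 0.42, adjusted p = 0.00251, adjusted p = 0.635 with an estimated correlation) lost it without mouse 2 of Low (0.0583). G1/S genes (0 of 23 called, median -0.35, adjusted p = 0.0237, adjusted p = 0.635 with an estimated correlation) and ribosomal genes (1 of 42 lower, median -0.16, adjusted p = 0.00762, adjusted p = 0.743 with an estimated correlation) lost it without mouse 2 of Low (0.642 and 0.333), and G1/S genes in cluster 6 alone (0.0973). Doublets kept also ended the calls of fatty acid oxidation (0.184), revival (0.0899), G1/S (0.710) and ribosomal genes (0.0906). For G1/S, 6 genes had an unadjusted p under 0.05 in edgeR, DESeq2 called 0, and edgeR called 1 higher and 6 lower with the replicate block. The mitochondrial genome list had a median of 0.18, a mean of -0.03 and a test that pointed down (adjusted p = 0.711). The autophagy lists were not called. Gabarap (log2 0.60 ± 0.12, adjusted p = 0.0228) and Vamp8 (log2 0.53 ± 0.14, adjusted p = 0.0466) were higher and the starter kinase Ulk1 (log2 -1.01 ± 0.26, adjusted p = 0.0465) lower. Ulk1 lost its call without each of the 4 sums (0.0763 to 0.199), Vamp8 without 3 (0.0744 to 0.186) and Gabarap without 2 (0.0629 and 0.109), all 3 with doublets kept (0.3301 to 0.443), and Ulk1 (0.0691) and Vamp8 (0.0640) in cluster 6 alone, while Map1lc3b (log2 -0.02 ± 0.11) and Sqstm1 (log2 0.26 ± 0.19, adjusted p = 0.409) were not called. Of 64 named genes called, 51, 55, 52 and 60 kept their call without mice 1 and 2 of High and mice 1 and 2 of Low in turn.

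Within T or NK lymphocyte-like cells of cluster 13, which are not epithelial, proliferation genes were lower in High. The plasma cell genes Igkc, Igha, Ighg2b and Jchain are among the 10 leading genes of this cluster, and B or plasma cell markers averaged 60.025 UMIs per cell in High and 1082 in Low (medians 0 and 1). At resolution 2 it split by gate into cluster 21 (7 High and 110 Low cells), led by these genes, and cluster 22 (113 and 3), whose 10 leading genes hold none of them. Mki67 was 9.85-fold lower (log2 -3.30 ± 0.34, adjusted p = 0.000398) and Top2a 6.21-fold lower (log2 -2.63 ± 0.38, adjusted p = 0.0955 with doublets kept). The epithelial genes Lyz1 (log2 7.18 ± 0.47), AY761184 (log2 7.24 ± 0.31), Defa24 (log2 7.12 ± 0.48) and Zg16 (log2 7.02 ± 0.28) were higher and moved with the free Paneth and goblet RNA of that library, and Fabp1 was higher (log2 1.85 ± 0.23, adjusted p = 0.00164). Of 3739 genes 29 were higher and 13 lower, 41 and 64 with the replicate block. Single sums left out gave 19 to 41 and 6 to 111. The immunoglobulin gene Iglc1 had 0 counts in High and was at least 16.0-fold lower by 3 counts over the group, and Iglc2 fell by log2 -3.52 ± 0.61. Of 19 named genes called, 14, 14, 17 (of 18) and 18 kept their call without mice 1 and 2 of High and mice 1 and 2 of Low in turn.

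Of the lists in lymphocyte-like cells, G2/M was lower (3 of 6 genes, 5 adjusted over the list alone, median log2 -2.35, adjusted p = 2.54e-10, adjusted p = 0.173 with an estimated correlation), as was G1/S (1 of 11, 5 adjusted over the list alone, median -1.17, adjusted p = 7.59e-07, adjusted p = 0.464 with an estimated correlation). Unfolded protein response genes were lower, as were the plasma cell markers (1 of 20, 8 adjusted over the list alone, 9 with the block, median -0.68, adjusted p = 2.62e-05, adjusted p = 0.701 with an estimated correlation). Antimicrobial genes (8 of 12, median 6.02, adjusted p = 1.4e-92, adjusted p = 0.0800 with an estimated correlation) and mucus genes (7 of 10, median 5.27, adjusted p = 2.25e-84, adjusted p = 0.0565 with an estimated correlation) were higher with the free RNA. MHC class II genes were higher (1 of 5, H2-Aa at log2 2.68 ± 0.48, median 1.12, adjusted p = 0.000343, adjusted p = 0.701 with an estimated correlation), a call lost without mouse 2 of Low (0.471). The mitochondrial genome (0 of 13 called by edgeR and by DESeq2, 7 at an unadjusted p under 0.05, 7 lower adjusted over the list alone, median -0.52, adjusted p = 0.00125, adjusted p = 0.892 with an estimated correlation) lost the call without mouse 1 of Low (0.269). Lipid absorption genes (1 of 9 higher, median 0.20, adjusted p = 0.0425, adjusted p = 0.621 with an estimated correlation) lost it with the replicate block (0.0616) and without mouse 2 of High (0.110) and mouse 2 of Low (0.661). With doublets kept the calls of unfolded protein response (0.638), lipid absorption (0.261) and MHC class II genes (0.475) were lost, and after thinning the first list pointed up without a call (0.742).

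The last question was whether the gate difference itself differs between enterocyte-like and stem-like cells. It was more positive in enterocyte-like cells for 725 of 11367 genes and in stem-like cells for 448 (1014 and 718 with the replicate block). Immediate early genes (median log2 difference 1.47, adjusted p = 9.09e-25), ribosomal protein genes (1.18, 1.3e-57) and cholesterol synthesis genes (0.98, 1.86e-12) were more positive in enterocyte-like cells, and brush border (-1.06, 1.24e-12) and G1/S genes (-1.23, 1.33e-05) in stem-like cells. With an estimated correlation the adjusted p-values were 0.112, 0.306, 0.306, 0.351 and 0.351. In both classes the gates lay mostly in different clusters, so these differences also compare clusters. The autophagy machinery and receptor lists did not differ detectably (adjusted p = 0.944 for both).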

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

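Tests of free RNA, of own expression, of stress (whole-library handling and the clusters that hold a class) and of Paneth-like cells among barcodes left out were chosen only after the result was seen; the tests of doublets, of the authors' filter on stem markers and of a library difference were planned.

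By an interaction term the gate difference was more positive in enterocyte-like cells for 725 and in stem-like cells for 448 of 11367 genes. Among the lists, tested on the interaction as an addition after seeing the data, the median difference (enterocyte-like minus stem-like) was 0.19 for nuclear oxidative phosphorylation, 0.98 for cholesterol synthesis, 1.47 for immediate early genes and 1.18 for ribosomal proteins. It was -0.75 for lipid absorption, -1.06 for brush border, -0.997 for mucus and goblet genes, -1.23 for G1/S, -0.70 for interferon response and -0.60 for MHC class II. None of these 10 list calls held with an estimated correlation (adjusted p from 0.112 to 0.860). Each class compares different clusters in the gates.

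Barcodes of at least 20% mitochondrial UMIs, which the authors left out, carry a signal that the main comparisons do not use, and those up to 25% enter the setting with all barcodes. Barcodes at or above 20% were 31.8% of the High and 74.5% of the Low library. Among those with at least 500 genes, the median log2 difference, High minus Low, was -1.19 for stem markers, 3.26 for goblet markers and 5.58 for Paneth markers.

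Paneth granule genes were higher in High in each of the 5 tested classes. A few droplets with a Paneth cell and a second cell are excluded as the cause, since 100% of the enterocyte-like and lymphocyte-like cells of High held a Paneth marker UMI. Expression by each class itself is argued against, since lymphocyte-like cells held 0.507 times the Paneth marker UMIs of enterocyte-like cells of the same library. Free Paneth RNA in the High droplets is a candidate explanation: the shares of the single markers differed between those 2 classes by a median absolute log2 of 0.141, as a single source would give. Goblet-like cells held 5.56 times the UMIs of enterocyte-like cells, more than free RNA alone would leave, and expression in these cells or shared droplets stay open for them.

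Immediate early genes were higher in High in enterocyte-like, cycling progenitor-like and goblet-like cells. Handling of the whole High library stays open, since the list's median of -0.23 in stem-like cells compares different clusters. In enterocyte-like cells the median in the single shared cluster (17 genes) was 0.129 of its class value (22 genes), with the list still called (adjusted p = 0.0191). Clusters rest on the same values, so this cannot tell clusters from a gate response. In goblet-like cells the median was 0.622 of the class value in the shared cluster, with 9 of 22 genes called. This cannot exclude a difference in cells, since at resolution 2 the class held 41 Low cells in place of 98. A response linked to the staining gate stays open and was not tested, as does one of some classes to sorting.

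Class shares differed between gates while 74.5% of the barcodes of Low had high mitochondrial shares. The authors' filter is argued against as the cause of the stem marker difference, which was log2 -1.53 in the kept cells, -1.19 in barcodes of at least 20% mitochondrial UMIs, and -2.12 in the 1831 High and 579 Low barcodes left out within the limits on genes, UMIs and mitochondrial share. For Paneth-like cells it is argued against among barcodes of up to 25% mitochondrial UMIs, since those left out were Paneth-like in 195 of 1380 of High and 1 of 977 of Low (exact 95% upper bound 0.569%). Above 25% the Paneth difference stays open, because free Paneth RNA differs between the libraries. A library difference cannot be told apart from the gate, since each gate has 1 library. A link between vesicle staining and cell type stays open.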

How the results depend on the processing

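Removal of cells with high doublet scores, a hashtag share of 60%, Paneth-like clusters left out, the single shared cluster of a class, and lists under the settings of the gene counts are tests chosen only after the result was seen. Unless a reason is stated, the cause was not tested.

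Of 4618 comparisons of 363 named genes with an alternative, 3866 kept their direction and side of the threshold, 656 lost the call, 45 gained it and 51 reversed in sign, 3 of these called in both and 35 in neither. Of 1001 comparisons of 83 list results, 772 kept both, 203 lost the call, 5 gained it and 21 reversed, 3 called in both and 11 in neither. RLE factors, removal of high doublet scores, a hashtag share of 60%, mitochondrial and ribosomal genes left out, and non-epithelial clusters left out moved no count of genes or lists by more than 1.5 times. No setting moved the median log2 of all genes in the whole population by more than 0.02. Within classes the shift passed 0.1 with DESeq2 in enterocyte-like cells (-0.126), without a filter in enterocyte-like (0.138), cycling progenitor-like (0.115), goblet-like (0.169) and lymphocyte-like cells (-0.123), and after thinning in lymphocyte-like cells (-0.167).

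With mouse as a replicate block (higher and lower in High), 3478 and 2887 genes were called in the whole population, 492 and 370 in stem-like, 1417 and 1478 in cycling progenitor-like and 1387 and 1011 in goblet-like cells, and 64 lower in lymphocyte-like cells. The interaction gave 718 genes more positive in stem-like cells. Of the named genes, 17 gained a call with the block and Mcm6 in enterocyte-like cells lost it (adjusted p = 0.0620). The block ended 5 list calls, added 3 in stem-like cells, and turned the mitochondrial genome list of the whole population to the opposite direction (0.934). It changed no other call of a named gene or list.

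DESeq2 called 1562 higher in the whole population, 365 and 397 (higher and lower) in enterocyte-like, 115 and 50 in stem-like, and 294 and 376 in cycling progenitor-like cells, 313 lower in goblet-like and 8 lower in lymphocyte-like cells. Without a filter on low counts, 2089 and 1097 were called in the whole population and 359 and 247 in stem-like cells, 50 and 110 in lymphocyte-like cells, and 1265, 1263 and 1532 higher in enterocyte-like, cycling progenitor-like and goblet-like cells. More genes are tested there. Thinning to 5000 UMIs left 39 and 19 in stem-like and 5 and 0 in lymphocyte-like cells, with fewer UMIs and cells. The 0 came from edgeR, which had 79 of 862 genes at an unadjusted p under 0.05; DESeq2 gave 8 without thinning. With doublets kept and cells clustered again, 147 were lower in stem-like and 21 in lymphocyte-like cells, and 49 higher and 18 lower in goblet-like cells. All barcodes that pass the wider filter gave 1658 and 1499 in the whole population, Paneth-like clusters left out 421 and 290, and an equal mix of classes, which uses fewer cells, 67 and 114. The single shared enterocyte-like cluster gave 21 and 8. Stem-like and cycling progenitor-like cells had no shared cluster with enough cells, and lymphocyte-like cells are 1 cluster, so that these gave no value.

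Leaving out each sum, with the lone sum of a gate assumed to vary like the other, gave ranges. They were 190 to 477 higher and 22 to 230 lower in the whole population, 200 to 1615 and 288 to 1514 in enterocyte-like, 123 to 228 and 50 to 130 in stem-like, 166 to 576 and 328 to 692 in cycling progenitor-like, 274 to 562 lower in goblet-like, and 19 to 41 and 6 to 111 in lymphocyte-like cells. The highest enterocyte-like counts came without mouse 2 of Low, which has 27 cells. Lists ranged from 5 to 9 higher in enterocyte-like, 3 to 5 lower in stem-like, 2 to 4 lower in goblet-like and 2 to 4 higher in lymphocyte-like cells.

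With an estimated correlation camera called 0 lists higher and 0 lower in each population except stem-like cells (2 and 0). Fry called 5 higher and 0 lower in the whole population, 1 and 0 in enterocyte-like, 2 and 0 in stem-like, 5 and 0 in cycling progenitor-like, 5 and 1 in goblet-like and 2 and 0 in lymphocyte-like cells. Fry asks whether a list moves on balance and compares it with no other genes. An equal mix of classes gave 8 lists higher and 6 lower, the shared enterocyte-like cluster 1 lower, and in lymphocyte-like cells doublets kept gave 8 lower and thinning 2 lower.

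With an equal mix of classes these genes of the whole population reversed, the first 3 called in both: Chga (log2 3.22), Chgb (5.07), Spdef (-0.95), Insm1 (0.90), Atoh1 (-0.23), Stx17 (-0.10), Edem1 (-0.23), Dnajb9 (-0.0130), Aurkb (-0.17), Gsta4 (-0.50) and Gsta1 (-0.96). So did genes not called in either: Nbr1 (-0.18), Fabp1 (-0.34), Fabp2 (-0.50), Sis (-0.30), Slc5a1 (-0.52), Ifi27l2b (-0.49), Irf1 (-0.17) and Map1lc3b (-0.0517). Lists that reversed there were autophagy machinery (adjusted p = 0.965), mitochondrial genome (0.702), lipid absorption (0.00114), brush border (1.53e-07), secretory progenitor (6.16e-06), G2/M (0.586), interferon response (0.176) and ribosomal proteins (0.176).

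Other reversals in the whole population were Cd74 after thinning (log2 0.0106), the mitochondrial genome list with all barcodes (adjusted p = 0.875), and the secretory progenitor list after thinning (0.662) and with all barcodes (0.981). Leaving out single sums gave Atp5b log2 -0.0386 to 0.12, Irf1 -0.10 to 0.20, Cd74 -0.29 to 0.14 and H2-Ab1 -0.42 to 0.0438. It gave adjusted p-values of 0.249 to 0.978 for the secretory progenitor list, 0.00657 to 0.749 for interferon response and 0.0737 to 0.615 for MHC class II, with a change of direction in each. In the shared enterocyte-like cluster Lipa had log2 0.27, Pmaip1 -1.23, H2-DMb1 0.12 and Map1lc3b -0.0593, and the lipid absorption list reversed (0.767). In stem-like cells thinning reversed Map1lc3b (log2 0.12), Sqstm1 (0.0427) and the secretory progenitor list (0.493). In goblet-like cells doublets kept reversed Clca1 (-0.11), Gsta1 (-0.90), Map1lc3b (0.14) and the lists of the unfolded protein response (0.324) and mucus (0.00178). Map1lc3b in goblet-like cells had 0.0404 without a filter, 0.18 after thinning and -0.0695 to 0.0372 without single sums, Sqstm1 -0.00242 in the shared cluster and -0.0530 to 0.49 without single sums, and Lgr5 -2.93 to 2.01. In lymphocyte-like cells Map1lc3b had -0.00385 with RLE, -0.0237 without a filter and -0.0647 to 0.0671 without single sums. Sqstm1 had -0.00558 with the replicate block, -6.37e-05 with RLE, -0.0157 without a filter and -0.54 to 0.43 without single sums, and the unfolded protein response list reversed after thinning (0.742).

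Shares, High minus Low in percent of cells, moved by more than the spread between mice as follows. Goblet-like cells differed by 12.1 and 12.4 at resolutions 0.5 and 2, 10.3 with doublets kept and 17.9 with all barcodes, stem-like cells by -29.4 at resolution 2 and -29.2 with doublets kept, cycling progenitor-like cells by 7.22 and enteroendocrine-like cells by -1.26 with all barcodes. Tuft-like cells had 2.80 at resolution 0.5 and changed sign to -1.58 at resolution 2 and -1.59 with doublets kept. Unnamed clusters had -33.1, -23.8, -11.2 and -20.8 in these 4 settings and -19.6 of epithelial cells only. A colonocyte-like class appeared only with doublets kept.

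Median UMIs per cell, High minus Low, were 405 over all classes, 3004.75 with all barcodes, -1932.25 in lymphocyte-like, 12144.2 in cycling progenitor-like, 4450.75 in enterocyte-like, 6347.25 in goblet-like, 3229.25 in stem-like and -7530.5 in unnamed cells. Median genes were -388, -297, -611.5, 1053.5, 506.5, 833, 402.5 and -661.5 in the same order. The median mitochondrial share was 0.865 over all classes, -0.624 with all barcodes, -2.22 in cycling progenitor-like, -0.338 in enterocyte-like, -3.16 in goblet-like, 1.26 in stem-like and 2.93 in unnamed cells. Depth limits the lymphocyte-like cells most, at medians of 2654 and 4586 UMIs.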

Other observations

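The tests of shared calls and of further class pairs were chosen only after the result was seen.

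Of the genes tested in both, stem-like and lymphocyte-like cells shared 27 genes higher and 0 lower in High, where independent calls would give 0.538 and 0.142. Cycling progenitor-like and goblet-like cells shared 222 and 175 (38.9 and 40.3), and enterocyte-like and goblet-like cells 122 and 45 (47.1 and 33.2). The classes share mice, libraries and free RNA, so calls need not be independent between classes without a gate effect. The interaction term gave 590 and 575 genes between enterocyte-like and goblet-like cells, and 67 and 75 between cycling progenitor-like and goblet-like cells (740 and 849, and 169 and 305, with the replicate block).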
